A study of Zea mays with 9 samples.

How the data were processed

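Endosperm RNA of 3 maize lines, B73, ae wx and sh1, was read on 9 Affymetrix arrays, 3 per line, 15 days after pollination. Per the labels, total RNA from field-grown plants was biotin labelled by the array maker's standard protocol, and the replicates are biological. The deposited table gives 1 intensity per probe set and array on a linear scale, called signal here. GCOS version 1.4 is named in the submitters' processing notes with no role, and the summary algorithm, the scaling target and any masks are not given in the sources used here. The table holds no detection calls. Its values have no negative numbers and 5 zeros, and they were used as deposited: 2% trimmed means over probe sets other than controls differed between arrays by 9.72%, below the 10% at which quantile normalization had been planned. All value columns belonged to samples of the series.

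The table holds 17734 probe sets, of which 113 are array controls and were left out of tests. Of the other 17621, the platform annotation gives 1 gene symbol for 1452 (1108 genes), several for 1 and none for 16168, and no gene was named from a probe set with several. For 1377 probe sets the Entrez identifier was found in the RefSeq gene table of Zm-B73-REFERENCE-NAM-5.0, which was used for names only, so no coordinates are given. Names other than placeholders were available for 1270 probe sets of 978 genes. Unnamed probe sets entered the counts of probe sets but no statement on genes, so the named genes are a small share of what was measured. Where 9 genes shared a name with a gene of another function they were kept out of the lists by hand.

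Probe sets were kept with a signal of at least 20% of their array's trimmed mean (124.7 to 136.8 across arrays) in at least 3 of the 9 arrays, which left 12414 and removed 5207. The arrays' depth cannot be counted as in sequencing, and signal near the level of dim probe sets limits small changes of low genes. Values were tested as log2(signal + 16) with limma 3.58.1 in R 4.3.3, by lmFit with 1 mean per line over all 9 arrays and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over the probe sets kept. A probe set was called at an adjusted p under 0.05. Fold changes are differences of line means on that scale. Standard deviations are of signal over 3 arrays, and standard errors come from the fit. All adjusted p-values for probe sets and genes are limma's. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

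For genes, the probe set with the highest mean log2 value stood for the gene, and other probe sets are given where they differed from it by over 1 (log2). Gene lists were tested with limma's camera at a preset correlation of 0.01 against the 843 genes measured, adjusted over the 13 lists with at least 5 measured genes: starch synthesis, sucrose and hexose metabolism, zeins, endosperm regulators, chaperones and folding enzymes of the endoplasmic reticulum, heat shock proteins, transfer cell markers, embryo and aleurone storage markers, amino acid and nitrogen metabolism, glycolysis and anaerobic metabolism, cell cycle and histones, ribosomal proteins and defence proteins. Markers of the embryo-surrounding region, green tissue markers, the anthocyanin and flavonoid pathway and lipid synthesis had fewer measured genes and are described only. Camera with an estimated correlation and fry, which tests whether a list moves one way without comparing it with other genes, were run beside it. Lists, tests, filters and the alternatives not named as added later were fixed before the data were examined. The removal by hand of genes with shared names was not part of the lists as set down then.

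The rule for named genes took the genes of the loci, in each comparison the 8 highest and 8 lowest called genes whose arrays did not overlap between the lines, up to 4 called members of each list (or, where none was called, the 2 brightest) and the 4 highest and 4 lowest genes of the overlap. Chance alone separates 3 arrays from 3 for 10% of genes. Not every gene that the rule took is named: some are only counted in their lists, most of them because leaving out 1 array ended the call, and 1 is not reported here. Genes named outside this rule are said to have been chosen after their values were seen. Beside the overlap of the comparisons with B73, which share 3 arrays, stand 20 simulated data sets of unchanged groups and the overlap of independent lists.

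The fit was tested on simulated data of the 12414 probe sets with 100 changed by 1.5-fold and 100 by 2-fold. With each line's own spread it recovered 64%, 68% and 66% of the 1.5-fold changes and 93%, 95% and 91% of the 2-fold changes in ae wx against B73, sh1 against B73 and ae wx against sh1, with 0 in the wrong direction. Unchanged probe sets called numbered 96, 102 and 5, and with a single spread for all lines 2, 5 and 9. A simulated shift of the starch synthesis list was called in each comparison, and in ae wx against sh1 with each line's own spread 1 list that had not been shifted was called too.

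Alternatives were no filter, a filter at 40%, pseudocounts of 1 and 64, quantile normalization, centring on the median, no intensity trend, array weights, a fit of only the lines compared, the replicate number as a block, leaving out each array, a 2-fold threshold, another choice of probe set per gene and other list tests. After the data had been seen, lists that kept the genes with shared names and a fit with sh1 replicates 2 and 3 averaged were added. The array's control probe sets, including spiked-in RNA and probe sets for both ends of housekeeping transcripts, were described but not tested. Of 66 probe sets for reporter genes, 5 passed the filter and 0 were called.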

Results

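RNA abundance was measured in maize (Zea mays) endosperm, the starch-storing tissue of the kernel, collected 15 days after pollination. Each of the 9 RNA samples was read on its own Affymetrix array, on which a probe set is a group of short probes summarised as 1 signal for a transcript. The samples came from 3 field-grown inbred lines with 3 replicates each, which the labels call biological. B73 is the line whose genome serves as the maize reference, the ae wx line is named for the amylose extender and waxy loci of starch synthesis, and the sh1 line is named for shrunken1, a sucrose synthase locus. No alleles are given by the labels, nor is it stated how either mutant line is related to B73, so effects of the named loci are not separable from other differences between the lines. Median signal per array lay between 241.2 and 256, and the 2% trimmed mean lay between 623.4 and 684. The number of arrays limits the precision of every value below.

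The lines separated from one another on the principal components of the 12414 probe sets tested. Component 1 held 57.5% of the variance and placed the B73 arrays at −66.8, −57.4 and −47.4, the ae wx arrays from 21.3 to 22.4 and the sh1 arrays from 34 to 36.3. Component 2 held 32.9% and placed ae wx from −41.7 to −39.9 and sh1 from 30.3 to 37.1. The median SD of a probe set between replicates was 0.18 on the log2 scale in B73, 0.07 in ae wx and 0.08 in sh1. B73 replicate 3 was the B73 array nearest to the mutant lines. The pair of arrays most alike was sh1 replicates 2 and 3 (r = 0.998 across probe sets). Their deviations from the mean of their line correlated at 0.406, against −0.857 to −0.24 for every other pair within a line. The labels do not say whether this pair came from separate ears, so n = 3 for sh1 rests on the word biological in the labels. With the pair averaged as 1, the calls of the starch synthesis and heat shock lists in ae wx against sh1 (adjusted p = 0.0586 for each) and of the endosperm regulators in sh1 against B73 (adjusted p = 0.051) ended. Ratios of 3′ over 5′ control signals, a sign of RNA quality, differed from B73 in both mutant lines, by 0.40 in ae wx and 0.43 in sh1 for actin, 0.09 and 0.58 for GAPDH, 0.36 and 0.14 for EF1a, and −0.34 and −0.39 for cyclophilin (log2). In all 3 comparisons, gene lists included, differences of RNA quality are therefore not separable from those of the lines. Controls with no maize target had mean signals of 40.4 in B73, 39.9 in ae wx and 41.7 in sh1, and where a gene was not above such controls in at least 1 array of a line, its signals are given in the comparisons below without a fold change.

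**Figure D1:**
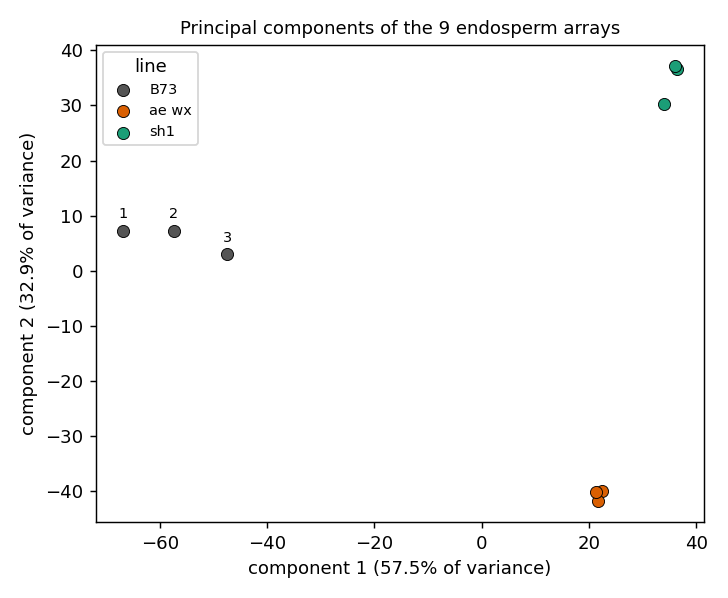
Principal components of log2(signal + 16) over 12414 probe sets, each point 1 array, with component 1 (57.5% of the variance) across and component 2 (32.9%) upward, and the replicate number printed for the B73 arrays. The B73 arrays lie at −66.8, −57.4 and −47.4 on component 1, while the ae wx and sh1 arrays lie at 21.3 or above.

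Of the genes at the named loci, wx1 was lower in the line named for it, sh1 was lower in the line named for it, and ae1 was not lower in the ae wx line. The gene wx1 encodes granule-bound starch synthase, the enzyme of amylose synthesis. Its signal was 4738 ± 812 (SD, n = 3) in ae wx, with single arrays at 4156, 5666 and 4392, and 14310 ± 700.1 in B73, with arrays at 15122, 13907 and 13913. The difference was 3.04-fold (log2 fold change −1.60 ± 0.10 SE, limma adjusted p = 1.14e-06), where this and every later fold change is on the log2(signal + 16) scale, which understates the change of low genes. In sh1, wx1 stood at 10330 ± 383 (9940, 10349 and 10706), 1.38-fold below B73 (adjusted p = 0.00357). The gene ae1 encodes starch branching enzyme IIb. It read 11774, 12085 and 11728 in ae wx, 10412, 8974 and 9995 in B73, and 10210, 9471 and 10062 in sh1. Its level in ae wx was 1.21-fold above B73 (log2 fold change 0.28 ± 0.06 SE, adjusted p = 0.00396), and its other probe set gave 0.49 (adjusted p = 0.00245). Because the labels name no ae allele and do not say whether its transcript is altered, the ae1 level does not check the label. The gene sh1, which encodes the main sucrose synthase of the endosperm, read 1686, 1843 and 1965 in the sh1 line against 18139, 16902 and 17372 in B73 and 15910, 16149 and 15900 in ae wx. Its level in the sh1 line was 9.48-fold below B73 (log2 fold change −3.25 ± 0.06 SE, adjusted p = 3.3e-10). The other probe sets of sh1 gave differences of 30.5-fold and 35.9-fold between these lines. In ae wx, sh1 differed from B73 by −0.13 ± 0.06 (SE, log2, adjusted p = 0.119), while one of its other probe sets was lower there (−0.67, adjusted p = 0.00156).

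**Figure D2:**
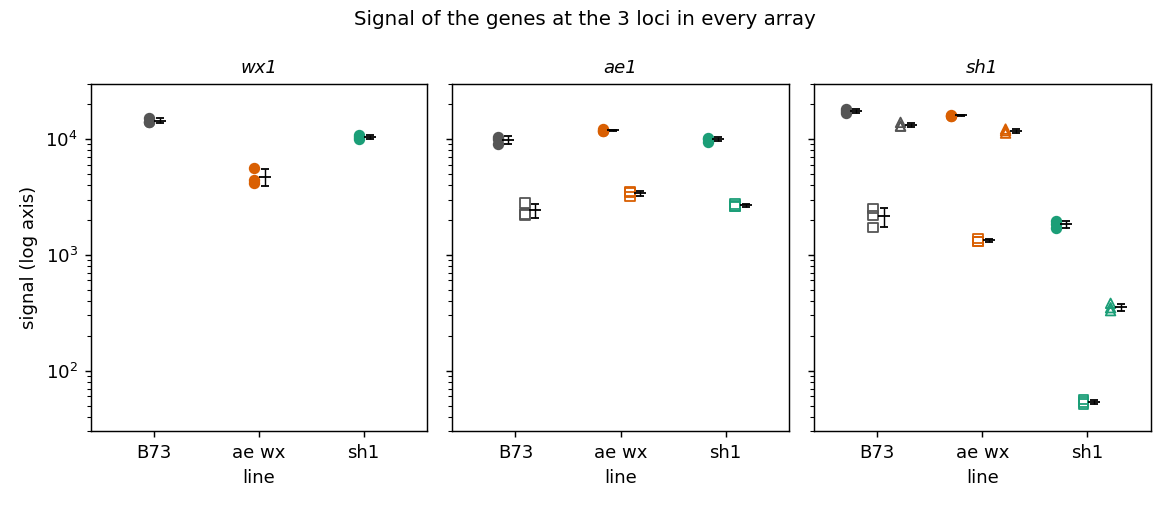
Signal (log axis) of wx1, ae1 and sh1 in every array of the 3 lines, with filled symbols for the probe set used for the gene and open symbols for its other probe sets; the black marks are the mean and SD of 3 arrays. The sh1 gene reads 1686 to 1965 in the sh1 line and 15900 to 18139 in the other lines, and wx1 reads 4156 to 5666 in ae wx.

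The comparison of ae wx with B73 sets the line named for starch synthesis loci against the reference line. Among named genes, f3h, which encodes flavanone 3-hydroxylase of the flavonoid pathway, was 13.5-fold higher in ae wx (1130 ± 3.46 against 69.5 ± 11.3, SD, n = 3, adjusted p = 1e-07). HRGP, which encodes a hydroxyproline-rich glycoprotein of the cell wall, was 42.8-fold lower (60.4 ± 13.3 against 3302 ± 859, adjusted p = 1.79e-08). The sucrose synthase gene sus2 was 13.6-fold lower (180.6 ± 19.3 against 2699 ± 672, adjusted p = 3.43e-07). Of 14 starch synthesis genes 10 were higher, and of 7 zein genes 4 were lower, but neither list was called (list adjusted p = 0.185 and 0.247). In all, 3604 of the 12414 probe sets were higher and 3020 lower, of which 909 and 679 differed by at least 2-fold, but here and in the other comparisons which direction had more calls depended on the scaling of the arrays.

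The other genes with the largest differences covered varied functions. Higher in ae wx were the glutathione S-transferase genes gst18 (242.2 ± 7.37 against 6.64 ± 1.86, SD, the latter not above controls with no maize target) and gst5 (log2 fold change 2.67 ± 0.23 SE), as well as CAF1 (3.19 ± 0.12), nthr3 (3.02 ± 0.12) and m26 (2.74 ± 0.12). The histone H2B gene his2b5 (2.57 ± 0.42) and MMT1, a methionine S-methyltransferase gene (329.9 ± 21.04 against 44.1 ± 6.98, SD, where B73 replicate 1 was not above those controls), were higher too. Lower were hmt4, a homocysteine S-methyltransferase gene (33.6 ± 3.23 against 1010 ± 408, SD, the former not above those controls), mtl2 (−3.77 ± 0.31 SE, log2) and MRP2 (−3.22 ± 0.09, with −0.90 from its other probe set). The pyruvate decarboxylase gene pdc2 was 7.32-fold lower, with values from −2.60 to −1.08 (log2) from its other probe sets. Also lower were tip3a (−5.17 ± 0.51) and tip3b (−3.81 ± 0.75), which encode water channels of the vacuolar membrane. Their B73 signals were uneven, with tip3a at 11620, 12090 and 2378 and tip3b at 1630, 2141 and 160.7 in replicates 1, 2 and 3.

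Among carbohydrate genes, 10 of the 14 measured starch synthesis genes were higher, 2 were lower and 2 were not called. Higher were sbe1, starch branching enzyme I (0.81 ± 0.11 SE, log2), and GBSSIIa (0.74 ± 0.10), and the lower genes were wx1 and zpu1, a pullulanase-type debranching enzyme (−1.54 ± 0.26). The list test gave adjusted p = 0.185. Of 10 genes of sucrose and hexose metabolism, 4 were higher, among them the fructokinase gene frk2 (0.58 ± 0.10) and the sucrose transporter gene sut1 (0.50 ± 0.09), and 2 were lower, sus2 and the glucose phosphate isomerase gene phi1 (−0.58 ± 0.11). Its list test gave adjusted p = 0.89, and the mean of the list had the opposite sign to its median. Of 13 glycolysis and anaerobic metabolism genes, 9 were higher and 1, pdc2, was lower. The alcohol dehydrogenase gene adh2 (1.43 ± 0.10) and the pyruvate decarboxylase genes pdc3 (1.21 ± 0.10) and pdc1 (1.15 ± 0.19) led those that were higher (list adjusted p = 0.185).

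Zeins are the storage proteins of maize endosperm. Of 7 measured zein genes 1 was higher and 4 were lower (list adjusted p = 0.247). The alpha zein gene az22z1, also known as floury2, read 18610 ± 246 against 11510 ± 242 in B73 (0.69 ± 0.11 SE, log2). Lower were the alpha zein genes az22z5 (−1.61 ± 0.12) and az19D1 (−0.93 ± 0.06) and the delta zein gene dzs18 (−0.55 ± 0.04), whose other probe sets gave −1.17, −1.53 and −5.28. Among 13 endosperm regulators 1 was higher and 4 were lower (list adjusted p = 0.302), with mez1, a Polycomb group gene, at −0.72 ± 0.15, the aleurone genes Sal1 and cr4 at −0.70 ± 0.08 and −0.60 ± 0.11, and the bZIP gene ohp2 at 0.46 ± 0.10. Of 14 genes for chaperones and folding enzymes of the endoplasmic reticulum 3 were higher, led by pdi5 (1.62 ± 0.11), and 5 were lower, led by pdi8 (−0.93 ± 0.18) and derlin1 (−0.85 ± 0.16), with list adjusted p = 0.247. Of 6 heat shock genes 1 was higher, hsp22 (1.42 ± 0.37), and 2 were lower (list adjusted p = 0.473). One of these was hsp70-4 (−0.40 ± 0.07), and the other, hsp101, was not called without B73 replicate 1 or 3 or any 1 of the ae wx arrays (−1.64 to −1.28).

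Cell cycle and histone genes numbered 7 higher and 2 lower of 10 (list adjusted p = 0.302), including the replication clamp gene pcna2 (1.42 ± 0.33 SE, log2), wee1 (0.92 ± 0.14) and cycD2 (−1.54 ± 0.17). Of 9 ribosomal protein genes 3 were higher and 1 was lower, with rpl39 at 1.28 ± 0.29, rpl29 at 0.95 ± 0.15 and RPS21 at 0.96 ± 0.25, which was 0.59 without B73 replicate 1. Amino acid and nitrogen genes were 2 higher and 3 lower of 8, with the aspartate kinase gene akh2 at 1.51 ± 0.12, the asparagine synthetase gene asn1 at 0.53 ± 0.14 and the cystathionine synthase gene cgs1 at −0.54 ± 0.14. Defence genes were 1 higher and 3 lower of 6, with bx6 of benzoxazinoid synthesis at 1.96 ± 0.16 (3.11 from its other probe set) and prp2 at −0.97 ± 0.11. Each of these last 3 lists had adjusted p = 0.668, and the median and mean of the defence list had opposite signs. Outside the list tests, f3h was the 1 gene called of 2 in the anthocyanin and flavonoid list, and FAD8, a fatty acid desaturase gene, was the 1 called of 4 in lipid synthesis (0.56 ± 0.12).

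Single markers of other kernel parts were called as well, but neither of their tested lists was. Of 6 transfer cell markers, which mark the basal layer facing maternal tissue, 5 were higher in ae wx and none lower (list adjusted p = 0.185). Signals of meg2 were 2085, 362.2 and 383.2 in the ae wx arrays and 81.6 to 144.4 in B73 (2.42 ± 0.60 SE, log2, and 1.61 without ae wx replicate 1). Those of bap2 were 1080, 263.6 and 253.8 against 40.9 to 90.1. The embryo and aleurone list had 3 lower and none higher of 5 (list adjusted p = 0.185), led by the globulin gene glb1 (−2.50 ± 0.31). Both measured green tissue markers were lower, psah1 at −2.01 ± 0.52, with B73 arrays at 545.8, 729.8 and 107.7, and me3 at −0.58 ± 0.11. The 1 marker of the embryo-surrounding region on the array was too dim to be kept.

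None of the 13 lists was called between ae wx and B73 by camera with the preset correlation. At an unadjusted p under 0.05 there was 1, glycolysis (p = 0.0164), with an estimated correlation there were 0 (lowest adjusted p = 0.634), and fry, which asks only whether a list moves one way, gave 8. Adjusted over the list alone, the counts were those above except for the endoplasmic reticulum list (3 higher and 6 lower) and the defence list (2 higher and 3 lower). B73 varied more between replicates than the mutant lines while the model shares 1 spread. In simulated data with each line's own spread, 96 of the unchanged probe sets were called for this comparison, against 2 with a single spread. The 96 were 36.1% of the simulated calls, where few probe sets were changed, so this share does not carry over to the real calls.

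The comparison of sh1 with B73 sets the line named for a sucrose synthase locus against the reference line. HRGP was lower (35.9 ± 5.76, not above controls with no maize target, against 3302 ± 859, SD, n = 3, adjusted p = 8.46e-09), and BCH2, a beta-carotene hydroxylase gene, was 12.5-fold lower (523 ± 8.95 against 6742 ± 430, adjusted p = 4.13e-10). The wound-induced proteinase inhibitor gene wip1 was 11.5-fold higher (1921 ± 738 against 162 ± 100.7, adjusted p = 6.37e-05), and the alternative oxidase gene aox1 was higher (536.3 ± 279 against 34.9 ± 2.86, the latter not above those controls, adjusted p = 4.3e-05). Of 13 endosperm regulators 9 were lower (list adjusted p = 0.0481, or adjusted p = 0.666 with an estimated correlation), and of 6 heat shock genes 4 were higher (list adjusted p = 0.34). In all, 3780 probe sets were higher and 3159 lower, of which 1074 and 691 differed by at least 2-fold.

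Further genes with the largest positive differences were the glutathione S-transferase genes gst42 (3.19 ± 0.28 SE, log2) and gst18 (156 ± 50.6 against 6.64 ± 1.86, SD), the ribosomal protein gene RPS21 (2.84 ± 0.25), hsp22 and meg2. The arrays of the sh1 line differed among themselves for several of these, with aox1 at 214.8, 673.8 and 720.3 and gst42 at 1290, 2906 and 2885. Further genes with the largest negative differences were hmt4 (−3.81 ± 0.28 SE, log2), the acetylcholinesterase gene ache1 (56.2 ± 2.59 against 570.8 ± 143, SD), the cystatin gene psei1 (−2.80 ± 0.13), acco20 of ethylene synthesis (−2.64 ± 0.14) and the expansin gene expB3 (−2.61 ± 0.20).

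The endosperm regulators were the 1 list called between sh1 and B73. Of its 13 genes 9 were lower, 1 was higher and 3 were not called, with a median of −0.49 (log2) and adjusted p = 0.0481, or adjusted p = 0.666 with an estimated correlation. Lower were mez1 (−1.39 ± 0.15 SE), the prolamin-box binding factor gene pbf1 (2247 ± 235 against 3645 ± 424, SD, −0.69 ± 0.10 SE), Nkd1, a zinc finger gene of aleurone differentiation (−0.67 ± 0.12), and Sal1 (−0.68 ± 0.08). The higher gene was fie2 of the Polycomb group (0.43). The members act in different programmes, from zein transcription to aleurone fate and chromatin. The regulator gene o2, named here after its values were seen, had been set down for the list but was not among the genes tested in it. Its probe sets gave 0.009 (adjusted p = 0.937) and −0.181 (adjusted p = 0.281) in sh1 against B73. In B73 replicate 3 the list stood lower than in the other B73 arrays (−0.23, percentile 2.6 of random lists), and without that array the list had adjusted p = 0.0127. The call ended without B73 replicate 1 (adjusted p = 0.0954), B73 replicate 2 (0.0862), ae wx replicate 1 (0.0598) or sh1 replicate 3 (0.0528). It also ended with no filter (0.129), quantile normalization (0.0691), median centring (0.0671) or only the lines compared (0.0614), and over all alternatives the adjusted p ran from 0.0127 to 0.666. Of the 10 splits of the B73 and sh1 arrays into 3 against 3, 8 gave at least 1 called list, the real 1 included. A count of 1 called list therefore does not set the real grouping apart.

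Of 6 heat shock genes 4 were higher in sh1 and 1, hsp70-4, was lower (list adjusted p = 0.34). Signals of hsp22 were 3103, 8259 and 8667 in the sh1 arrays against 671.9 to 1269 in B73 (2.82 ± 0.37 SE, log2). Those of hsp18f were 2749, 11730 and 12030 against 1337 to 1736 (2.27 ± 0.46), and hsp18a was higher as well (1.94 ± 0.44). The gene hsp18c was not called (1443, 8605 and 8564 against 2083 to 2567 in B73). Replicate 1 was the lowest sh1 array for each of these, and without it the list had adjusted p = 0.0253. That value rests on sh1 replicates 2 and 3, which the labels do not say came from separate ears. With replicate 1 kept and this pair averaged as 1, the list had adjusted p = 0.448. The gene hsp101 (1.77 ± 0.53) was not called without B73 replicate 2, sh1 replicate 2 or sh1 replicate 3 (1.36, 1.43 and 1.42). Genes for chaperones and folding enzymes of the endoplasmic reticulum were 5 higher and 1 lower of 14 (list adjusted p = 0.339), with pdi5 at 1.67 ± 0.11, bip2, which encodes a luminal binding protein, at 1.08 ± 0.12 and pdi10 at 0.74 ± 0.15.

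Starch synthesis genes in sh1 were 2 higher, 4 lower and 8 not called of 14 (list adjusted p = 0.808). The starch synthase gene su2 was higher (1.57 ± 0.38 SE, log2), with B73 arrays at 1225, 2973 and 4371 and sh1 arrays at 8552, 6767 and 7341, and zpu1 was lower (−2.18 ± 0.26). Genes of sucrose and hexose metabolism were 4 higher and 4 lower of 10 (list adjusted p = 0.696). Besides sh1 itself, sus2 was lower (−2.60 ± 0.21), and the fructokinase genes frk1 (0.86 ± 0.09) and frk2 (0.82 ± 0.10) were higher. In both lists the median and the mean had opposite signs. Glycolysis and anaerobic metabolism genes were 9 higher and 1 lower of 13 (list adjusted p = 0.086), led by adh2 (1.66 ± 0.10), pdc3 (1.24 ± 0.10) and pdc1 (1.13 ± 0.19). Zein genes were 1 higher, 3 lower and 3 not called of 7 (list adjusted p = 0.293), with az22z5 at −1.34 ± 0.12, az22z1 at −1.26 ± 0.11 and the gamma zein gene gz50 at −0.41 ± 0.04. The 1 higher was dzs18 (0.13 ± 0.04), not called without B73 replicate 3 (0.10) or any 1 of the sh1 arrays (0.12 to 0.14), and lower at another of its probe sets (−0.86). Its signals of 21770 ± 895 in B73 and 23820 ± 365 in sh1 (SD) lay near the highest of an array (25470 to 28370). Whether such bright signals still follow RNA amounts was not tested, so small or absent zein differences in any comparison may understate those of RNA.

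Cell cycle and histone genes were 6 higher and 2 lower of 10 in sh1, with pcna2 at 2299 ± 117 against 638.1 ± 409 (SD) and cycD2 at −1.47 ± 0.17 (SE, log2), and ribosomal protein genes were 4 higher and none lower of 9, with rpl39 at 1.20 ± 0.29 (list adjusted p = 0.497 for each). Defence genes were 2 higher, wip1 and bx6 (1.99 ± 0.16, and 3.60 from its other probe set), and 1 lower of 6 (list adjusted p = 0.703). Amino acid and nitrogen genes were 3 higher and 1 lower of 8 (list adjusted p = 0.808, median and mean of opposite sign), with akh2 at 1.18 ± 0.12 and the glutamine synthetase gene gln5 at −1.04 ± 0.16. Transfer cell markers were 5 higher and none lower of 6 (list adjusted p = 0.278), with BETL1 at 1.03 ± 0.16 and meg2 at 1475, 704 and 611 in the sh1 arrays. Of 5 embryo and aleurone markers only glb1 was called, lower (−2.47 ± 0.31, list adjusted p = 0.321). In the small lists f3h was higher (1.23 ± 0.17, 1 of 2 called), me3 was lower (−1.52 ± 0.11, 1 of 2 called) and 2 of 4 lipid synthesis genes were higher.

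Besides the endosperm regulators, glycolysis passed an unadjusted p under 0.05, which made 2 lists of 13, and fry called 11. With genes of shared names kept in the lists, camera called glycolysis as well (adjusted p = 0.0456). Adjusted over the list alone, the only count that differed was that of the green tissue markers (2 lower). Simulated data with each line's own spread gave 102 unchanged probe sets called here, against 5 with a single spread. The 102 were 36.7% of the simulated calls, a share that does not carry over to the real calls either.

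The comparison of ae wx with sh1 is the direct test of differences between the mutant lines. BCH2 was 16.2-fold higher in ae wx (8730 ± 258 against 523 ± 8.95, SD, n = 3, adjusted p = 3.2e-10), and gst42 was lower (49.2 ± 6.69, in replicate 3 not above controls with no maize target, against 2360 ± 927, adjusted p = 5.51e-07). The cystatin genes psei1 and cpi2, which encode inhibitors of cysteine proteinases, were 11-fold and 7.75-fold higher in ae wx. Of 14 starch synthesis genes 8 were higher in ae wx, and 7 of 14 endoplasmic reticulum genes and 4 of 6 heat shock genes were lower. These were the 3 lists called, and none was called with an estimated correlation (adjusted p = 0.629, 0.326 and 0.756). In all, 2213 probe sets were higher in ae wx and 2331 lower, of which 418 and 602 differed by at least 2-fold. The shared spread of the fit includes that of B73, which varied more between replicates. With only these lines fitted, 3265 probe sets were higher and 3466 lower.

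Other genes with the largest positive differences were nthr3 (2.79 ± 0.12 SE, log2), f3h (2.53 ± 0.17), PEAMT of choline synthesis (2.14 ± 0.09), MMT1 (1.98 ± 0.14) and sh1 (3.12 ± 0.06, and 4.27 and 4.99 from its other probe sets). Lower in ae wx were hsp101 (−3.37 ± 0.53), hsp18f (−3.19 ± 0.46), the aldehyde dehydrogenase gene rf2c (37.4 ± 3.15, not above controls with no maize target, against 433.4 ± 76.1, SD), aox1 (43.9 ± 4.28 against 536.3 ± 279, SD), the superoxide dismutase gene Sod4A (−2.88 ± 0.11), lim1 (−2.86 ± 0.21) and GP (−2.74 ± 0.13).

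Of 14 starch synthesis genes 8 were higher in ae wx, 2 were lower and 4 were not called, with a median of 0.27 (log2) and adjusted p = 0.0341, or adjusted p = 0.629 with an estimated correlation. Higher were sbe1 (0.71 ± 0.11 SE) and AGP2, a gene of ADP-glucose pyrophosphorylase (0.54 ± 0.08). The lower genes were wx1 (−1.14 ± 0.10), which lies at a locus in the name of the ae wx line, and su2 (−1.09 ± 0.38). The latter was not called without B73 replicate 2 or any 1 of the ae wx and sh1 arrays (−1.26 to −0.91). The call of the list ended without ae wx replicate 2 (adjusted p = 0.0858), sh1 replicate 2 (0.0561) or sh1 replicate 3 (0.0621). It also ended with quantile normalization (0.0512), median centring (0.0518) or no intensity trend (0.0643), and over all alternatives its adjusted p ran from 0.0085 to 0.629.

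Of 14 genes for chaperones and folding enzymes of the endoplasmic reticulum 7 were lower in ae wx and none higher (median −0.38, adjusted p = 0.0335, or adjusted p = 0.326 with an estimated correlation). They included the luminal binding protein genes bip2 (1522 ± 168 against 3995 ± 332, SD) and bip1 (3006 ± 151 against 6016 ± 667), and pdi8 (−1.28 ± 0.18 SE, log2) and derlin1 (−1.15 ± 0.16). Of 6 heat shock genes 4 were lower and none higher (median −1.79, adjusted p = 0.0341, or adjusted p = 0.756 with an estimated correlation). Beside hsp101 and hsp18f these were hsp18a (−2.17 ± 0.44) and hsp22 (−1.40 ± 0.37), the latter not called without sh1 replicate 2 (−1.18) or sh1 replicate 3 (−1.14). The heat shock call ended without B73 replicate 1 (adjusted p = 0.0639), B73 replicate 3 (0.0659), ae wx replicate 1 (0.0555), sh1 replicate 2 (0.0561) or sh1 replicate 3 (0.0623), and with only the lines compared (0.101) or no intensity trend (0.0626). Over all alternatives the adjusted p ran from 0.0085 to 0.326 for the endoplasmic reticulum list and from 9.81e-05 to 0.756 for the heat shock list.

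The endosperm regulators were 6 higher and 1 lower of 13 in ae wx (list adjusted p = 0.147), including Nkd1 (0.66 ± 0.12 SE, log2), mez1 (0.68 ± 0.15) and ohp1 (0.61 ± 0.09). Zein genes were 2 higher and 2 lower of 7, with az22z1 at 1.96 ± 0.11, az19D1 at −0.86 ± 0.06 and dzs18 at −0.68 ± 0.04 (−0.66, −1.31 and −5.39 from its other probe sets), and the median and mean of the list had opposite signs. Genes of sucrose and hexose metabolism were 2 higher, sh1 and the invertase gene incw1 (0.50 ± 0.12), and 2 lower of 10, sus2 (−1.16 ± 0.21) and frk1 (−0.57 ± 0.09). Glycolysis and anaerobic metabolism genes were 2 higher and 2 lower of 13, with pdc2 at −2.30 ± 0.14 (−1.89 to −0.79 from its other probe sets) and GPC1 at −0.66 ± 0.07. Amino acid and nitrogen genes were 2 higher and 2 lower of 8, with gln5 at 1.06 ± 0.16 and the S-adenosylmethionine synthetase gene sam2 at −0.46 ± 0.06. Cell cycle and histone genes were 1 higher and 1 lower of 10. Ribosomal protein genes were 0 higher and 1 lower of 9, RPS21 (−1.88 ± 0.25). Embryo and aleurone markers were 0 higher and 1 lower of 5. No transfer cell marker of 6 was called, with meg6 at −0.19 ± 0.11 and BETL1 at −0.36 ± 0.16. Each of these lists from the zeins on had adjusted p = 0.832. Defence genes were 0 higher and 2 lower of 6, wip1 (−2.51 ± 0.41 SE, log2) and prp2 (2171 ± 121 against 4353 ± 284, SD), with list adjusted p = 0.358. In the small lists f3h was the 1 called of 2, me3 the 1 called of 2 (0.94 ± 0.11) and 1 of 4 lipid synthesis genes was lower.

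Of the 13 lists 4 passed an unadjusted p under 0.05, 3 passed after adjustment, 0 passed with an estimated correlation and fry called 6. Adjusted over the list alone, starch synthesis had 9 higher and 2 lower, glycolysis 1 higher and 2 lower, and cell cycle and lipid synthesis none.

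**Figure D3:**
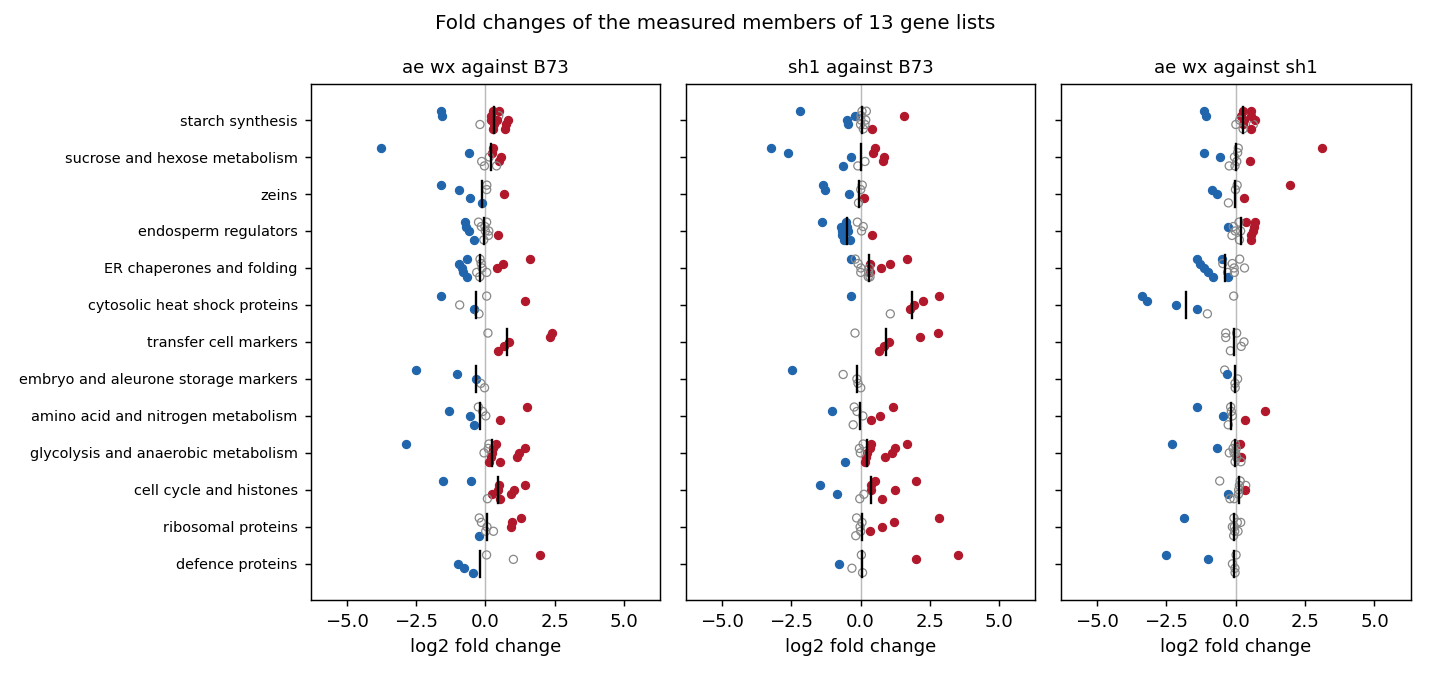
Log2 fold change across, for each measured member (point) of 13 gene lists in the 3 comparisons, with filled red points called higher in the first line, filled blue points called lower, open points not called, and a black bar at the median of the list. Endosperm regulators in sh1 against B73 have 9 of 13 points called lower, and no heat shock or endoplasmic reticulum gene is called higher in ae wx against sh1.

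Both mutant lines were set against the same 3 B73 arrays, and many of the same probe sets were called in the same direction. HRGP and hmt4, with values given above, sus2 (log2 fold change −3.76 in ae wx and −2.60 in sh1) and tip3a (−5.17 and −2.52) were lower in both. Higher in both were gst18, with signals given above, CAF1 (3.19 and 2.60), his2b5 (2.57 and 2.70) and gst5 (2.67 and 2.47). In all, 2473 probe sets were higher in both and 1911 lower in both, 583 and 338 of them by at least 2-fold in both. Independent lists of these sizes would share 1097 and 768.5. Simulated groups with no effect shared 6.2 and 6.05 on average, with all arrays, B73 included, drawn with noise independent between probe sets. Deviations common to many probe sets of the real B73 arrays, as in replicate 3, were not simulated, so these values may understate what sharing arrays gives. Across probe sets the fold changes had a covariance of 0.48 against 0.02 in that simulation, while their correlation of 0.67 lay below the 0.80 that shared arrays alone gave there. The 3 B73 arrays cannot be divided so that each part keeps 2 arrays, and part of the excess may come from sharing them. In opposite directions 365 probe sets were called.

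**Figure D4:**
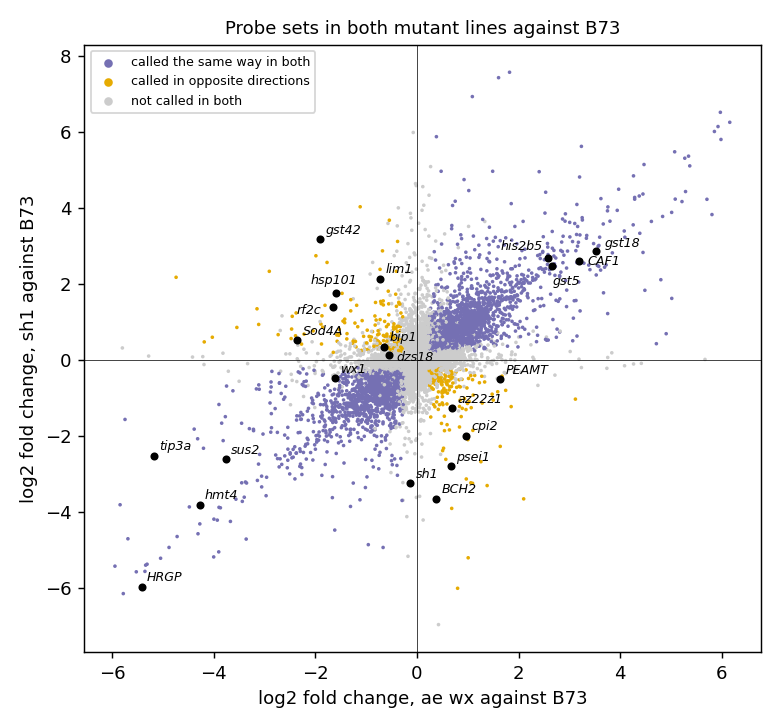
Log2 fold change of each of the 12414 probe sets in ae wx against B73 (across) and in sh1 against B73 (upward), with purple points called the same way in both, yellow points called in opposite directions and named genes in black. The gene sus2 lies at −3.76 and −2.60, and BCH2 lies at 0.37 and −3.65.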

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

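The tests of B73 replicate 3, of dim probe sets and of the spike-in controls below were chosen after the results had been seen, while those of cross-hybridising probe sets and of sequence differences were set down before.

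Of genes with a name, 29 were called in opposite directions from B73 in the mutant lines, which drew attention because most shared calls went the same way. Differences between ae wx and sh1 are given here for those that the rule for named genes took. These differences also passed their own test, which the choice of such genes makes nearly certain. Lower in ae wx and higher in sh1 were gst42 (fitted log2 difference ae wx minus sh1 −5.10), hsp101 (−3.37), rf2c (−3.06), Sod4A (−2.88), lim1 (−2.86), bip1 (−0.99) and dzs18 (−0.68). The sizes for gst42 and rf2c are uncertain, since 1 ae wx array of gst42 and the ae wx mean of rf2c (37.4) were not above controls with no maize target. From B73, hsp101 was not called in ae wx without B73 replicate 1 or 3 or any 1 of the ae wx arrays (−1.64 to −1.28), nor in sh1 without B73 replicate 2, sh1 replicate 2 or sh1 replicate 3 (1.36, 1.43 and 1.42). The slightly higher level of dzs18 in sh1 against B73 was not called without B73 replicate 3 (0.10) or any 1 of the sh1 arrays (0.12 to 0.14). Higher in ae wx and lower in sh1 were BCH2 (4.02), psei1 (3.46), cpi2 (2.96), PEAMT (2.14) and az22z1 (1.96).

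The array's control probe set for the 3′ end of GAPDH, which entered no test, read 2009 ± 267 (SD, n = 3) in sh1, 699.3 ± 88.5 in ae wx and 172.3 ± 11.3 in B73. Its probe set for the 5′ end read 30.7, 33.6 and 32.9 on average in B73, ae wx and sh1, and the one for the middle read 5134 to 5255 in the mutant lines and 5072 in B73.

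On the log2 scale B73 replicate 3 lay 0.213 of the way from the other B73 arrays to the mutant lines across the kept probe sets. Both differences behind this fraction subtract the mean of those B73 arrays, which can raise it. Admixture of mutant RNA to that sample is argued against by 38 probe sets dim in the other B73 arrays and bright in both mutant lines. On linear signal, a scale unlike that of the 0.213, their median fraction was 0.0041, although over 21 probe sets of the reverse kind it was 0.285. Admixture at the latter fraction would raise the dim probe sets as well. After quantile normalization the fraction was 0.214. A single factor for the whole array hardly enters this measure, because the mutant differences lie on both sides of 0, so the value does not decide on scaling. An earlier state of development remains possible, since the cell cycle and histone list stood at percentile 98.2 of random lists in this array against the other B73 arrays. However, the heat shock list at percentile 99.9, the transfer cell list at 0.3 and the defence list at 0.9 were at least as extreme, so development is not singled out. RNA quality was not tested here and stays open too. The 3′ over 5′ ratio (log2) of actin was 0.539 in replicate 3 against −0.079 and 0.056 in replicates 1 and 2. That of cyclophilin was 0.226 against 0.542 and 0.438, and that of EF1a 1.205 against 1.072 and 1.148, each on the side of the mutant lines. Those of ubiquitin and GAPDH lay between the other B73 arrays.

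Probe sets of 1 gene differed by over 1 (log2) in ae wx against B73 in 12% of 351 pairs from 158 genes, as for dzs18, his1 and o2. Noise of dim probe sets may account for part of this, since the share was 4.41% over 136 pairs of bright probe sets, which leaves the question open. Cross-hybridisation stays open too, since plain probe sets differed in 7 of 60 pairs (11.7%, exact 95% interval 4.82% to 22.6%) and other pairs in 12%, which is too few pairs to decide. Sequence differences of the lines under the probes could give the same 12%, and neither probe sequences nor those of the mutant lines were used. For single genes a fold change from 1 probe set therefore carries that doubt, and 18, 16 and 5 pairs were called in opposite directions in ae wx against B73, sh1 against B73 and ae wx against sh1.

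Spike-in controls were dimmer in the mutant lines than in B73, by −0.23 and −0.50 (log2, ae wx and sh1) for hybridisation controls and by −0.48 and −0.74 for poly-A controls. With 1 scaling factor per array both kinds would shift alike, and the poly-A controls shifted by a further −0.245 in sh1 and −0.246 in ae wx. The SD of single arrays within lines was 0.13, and both shifts rest on the same B73 arrays, which leaves the question open. An intensity bias behind the calls stays open as well, since the median fold change over deciles of signal, at most 0.105 from 0, comes after scaling per array and from probe sets that go both ways (SD 0.624 to 1.138 within deciles). A change in the total RNA per cell would not show in data scaled per array.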

How the results depend on the processing

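Keeping genes with shared names in the lists and averaging sh1 replicates 2 and 3 as 1 were chosen after the data had been seen. Of 187 results on named genes and 8 on lists called in some setting none changed direction under another setting with the same probe set per gene, but another probe set of the gene had the opposite sign for dzs18 (0.13 and −0.86, both called) and his1 (−0.84 and 0.17) in sh1 against B73 and for pdk1 (0.15 and −0.43) in ae wx against sh1. A further his1 probe set gave −5.22 in sh1 against B73. In ae wx against B73 that probe set gave −5.04 and another of his1 gave 0.68, both called. Of 31 further list results, called in no setting, 11 had a median of another sign in at least 1 setting, so those medians are not given. Levels held closely: leaving out 1 array gave −1.74 to −1.52 for wx1 in ae wx, 0.22 to 0.32 for ae1 in ae wx and −3.30 to −3.19 for sh1 in sh1. With at least a 2-fold change, calls fell to 909 higher and 679 lower in ae wx against B73, 1074 and 691 in sh1 against B73, 418 and 602 in ae wx against sh1, and 921 shared. Which direction had more calls depended on the scaling and turned in all 3 comparisons with quantile normalization: quantile normalization and median centring gave 3276 and 3392 higher and 3377 and 3229 lower in ae wx against B73, 3223 and 3217 higher and 3798 and 3780 lower in sh1 against B73, and 2462 and 2637 higher and 2139 and 2030 lower in ae wx against sh1. The last also turned with no filter (2606 higher and 2593 lower), and with array weights it had 3886 higher and 4133 lower. A fit of only the lines compared gave 3195 higher and 2708 lower in ae wx against B73 and 3193 and 2684 in sh1 against B73. In ae wx against sh1 it gave 3265 and 3466, so the smaller number of calls between the mutant lines depended on the fit. Leaving out 1 array gave 2925 to 3989 higher and 2490 to 3495 lower in ae wx against B73, 3160 to 4191 and 2640 to 3613 in sh1 against B73, 1616 to 2762 and 1715 to 2873 in ae wx against sh1, and 3693 to 5336 shared.

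Gene lists depended most on the processing. For sh1 against B73, where 1 list was called, there were 0 with no filter, quantile normalization, median centring, only the lines compared, an estimated correlation or sh1 replicates 2 and 3 averaged, 2 with array weights or shared names kept, 11 with fry and 0 to 2 without 1 array. For ae wx against sh1, where 3 were called, there were 4 with the stricter filter, 2 with quantile normalization, median centring or only the lines compared, 1 with no intensity trend or sh1 replicates 2 and 3 averaged, 0 with an estimated correlation, 6 with fry and 1 to 3 without 1 array. For ae wx against B73 there were 1 with array weights, 8 with fry and 0 without any 1 array. Fry asks another question of the lists, an estimated correlation widens the spread allowed for, and the cause of the other changes was not tested. Signal near the level of dim probe sets limits what can be said of low genes.

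Across all kept probe sets, arrays with the same replicate number did not deviate together, with correlations from −0.231 to 0.136 over 9 pairs, 1 of them above 0.1. Single genes could differ from this. Among the transfer cell markers named above, replicate 1 was the highest array in both mutant lines for meg2, bap2 and BETL1, but not for meg6. With the number as a block there were 3399 higher and 2806 lower in ae wx against B73, 3554 and 2922 in sh1 against B73, 1938 and 2082 in ae wx against sh1, 4051 shared, and 0, 1 and 3 lists.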

Other observations

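The splits for the counts of probe sets were chosen after those counts had been seen, while the splits for the gene lists and for the shared calls were set down before.

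Genes in this paragraph and the next, other than his2b5, gst42, gst5 and gst18, lay outside the rule for named genes and were chosen after their values had been seen. The regulator gene o2, which encodes a bZIP activator of zein genes, had a probe set at 2051 ± 143 (SD, n = 3) in ae wx, 7393 ± 675 in B73 and 7428 ± 439 in sh1, with −1.84 ± 0.09 (SE, log2, limma adjusted p = 1.44e-07) in ae wx against B73. The other o2 probe set gave −0.18 (adjusted p = 0.297) for the same comparison. In ae wx against sh1 these probe sets gave −1.849 and 0.003. Although set down for the endosperm regulators, o2 was not among the 13 genes tested in that list. Picked for going against gst42, the glutathione S-transferase gene gst37 read 415.5 ± 51.7 in ae wx, 200.8 ± 54.4 in B73 and 136.4 ± 11.6 in sh1. In the same order gst10 read 169.4, 115.7 and 58.5, and gst23 read 197.1, 116.4 and 90. By contrast, gst5 and gst18 were higher in both mutant lines than in B73, and the family was not tested. The water channel gene tip4d read 221.3 ± 33.5 in ae wx, 517.3 ± 86.2 in B73 and 961.3 ± 113 in sh1, and the cellulose synthase gene CesA-4 read 46.2 ± 4.67, 128 ± 10.04 and 186.6 ± 8.72. The haemoglobin gene Hb read 357.7 ± 12.2 in sh1 against 149.9 ± 14.1 in B73 (1.18 ± 0.09).

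Of 3 genes that were uneven within B73 no test as a group was made. In B73 replicates 1, 2 and 3, nfd101 read 206.6, 341.9 and 1124 against means of 1774 in ae wx and 1850 in sh1. The histone H2B gene his2b5 read 377.9, 648.5 and 1793, and nfd106 read 69.2, 89.2 and 226.2.

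Probe sets with signals under 100 in every array of B73 and over 500 in every array of both mutant lines numbered 25, and 14 were the reverse. In ae wx alone 6 were dim and 4 bright in this sense, and in sh1 alone 8 were dim and 15 bright.

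With 6 arrays there are only 10 splits of 3 against 3, too few for a share under 0.05. The calls of probe sets numbered 6624, 6939 and 4544 for ae wx against B73, sh1 against B73 and ae wx against sh1, and the highest of any other split was 0. For gene lists the real counts were 0, 1 and 3 and the highest others 3, 3 and 2. In sh1 against B73, 8 of the 10 splits, the real 1 included, gave at least 1 called list. Of 100 splits of all 9 arrays into 3 groups only the real 1 reached 4384 probe sets called the same way in both mutant lines against B73, and the highest other gave 2434, so random assignment of arrays is argued against for that count. Splits that mix the clearly separate lines widen the spread, so this result does not show how much the mutant lines share.

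Log2 ratios of 3′ over 5′ control signals were 0.40 in B73, 0.06 in ae wx and 0.02 in sh1 for cyclophilin, 0.17, 0.57 and 0.60 for actin, −0.07, 0.15 and 0.12 for ubiquitin and −0.10, −0.01 and 0.48 for a further pair of GAPDH probe sets. For EF1a the ratio was 1.14 in B73 and higher by 0.36 in ae wx and 0.14 in sh1. The ratios were higher in both mutant lines than in B73 for 4 of the 5 transcripts.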
